A study of Homo sapiens with 6 samples.

How the data were processed

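RNA was sequenced from 6 libraries of Huh7 cells, a human hepatoma line. Per the labels, 3 libraries came from cells given a scrambled control siRNA (siControl) and 3 from cells given an siRNA against ASGR1 (siASGR1), harvested 72 h after transfection. Libraries were made from 1 µg of total RNA with a TruSeq RNA kit, per the labels' protocols. The labels number the libraries 1 to 3 in each group and do not say whether they came from separate cultures on separate days, so p-values measure the spread between these libraries, which may be technical.

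Reads were processed by the authors with bcl2fastq 2.17.1.14, cutadapt 1.9.1 and HISAT2 2.0.1 on hg19, per the submitters' processing notes. The counting program, its strand setting and the gene annotation are not given in the sources used here. The authors deposited FPKM values (fragments per kilobase of exon, scaled to library depth), rounded to 2 decimals, for 57905 Ensembl gene IDs in 1 table of the whole series and in 1 file per library. Although the table of the whole series is named as raw counts, its values are FPKM. The design fixed beforehand had assumed counts, so its written fallback for other units was used: limma on log2(FPKM + 1). Values of the table of the whole series were used, and those of the single files were set as an alternative before the data were examined. The 7 deposited tables were compared value by value, and ASGR1 was the only gene that differed.

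Because FPKM are whole reads divided by length and depth, the depth behind each library was recovered from the steps between low values, with exon lengths of GENCODE v29 for the 52338 IDs that have one there. Values of up to 20 reads were examined in genes short enough for rounding to matter little (5923 to 7184 per library). Between 93.6% and 94.5% came out as whole reads within rounding, against 11.6% to 12.6% by chance. The depth was fitted on overlapping values to make this share highest, so it is not an independent check. Reads rebuilt in this way were used only for alternatives, for a check of duplicate deposits and for the limit that 0 reads (fewer than 3) allows. Such limits cover counting error only. Chi-square over its degrees of freedom was 2.58 to 5.64 for pairs of libraries of the same group, so no pair agreed within sampling noise. Gene symbols were found for 39538 IDs (68.3%). Coordinates are those of GENCODE v29 on GRCh38, since the tables carry none.

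Genes with FPKM of at least 1 in at least 3 of the 6 libraries were tested (13568 genes). limma 3.58.1 in R 4.3.3 was fitted with the group as the only term, with an empirical Bayes prior that follows the expression level, two-sided, with Benjamini-Hochberg adjustment, and genes were called at an adjusted p under 0.05. The filter and the form of the prior were chosen once the unit was known; the filter was set before results were seen, and the prior was settled in an exploratory fit. Fold changes from the fit are on the log2(FPKM + 1) scale, which understates changes of low genes; folds of mean FPKM are given as such. FPKM are relative to each library's total. Scaling by median-of-ratios factors, tried after seeing the data, raised the median log2 fold change of all tested genes by 0.12, from -0.134 to -0.015. The shift differs between genes and is smaller for low ones, since 1 is added before the logarithm: the median of the fibroblast markers moved from -1.097 to -1.027.

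Also beforehand, 29 gene lists were fixed from textbook knowledge, of which 26 had at least 5 measured members. Each was compared with all other tested genes by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over those 26 lists. The genes named were chosen by a rule also fixed beforehand: 20 genes whatever their values, the 12 called genes with the largest change in each direction among those with a symbol, a mean level of at least 1 and no overlap between groups, and up to 4 called members of each list with the smallest p-values. The level was written for log2 CPM and was applied to log2(FPKM + 1). Some genes that this rule takes are not reported here. Other names are said to have been chosen after their values were seen.

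The fit was tested on simulated reads for 13027 genes with the real depths. Of 50 genes changed at each size, it recovered 24% at a fold of 1.2, 82% at 1.5, 100% at 2 and 100% at 4. It made 13 false calls, 7.8% of its calls. The simulation changed only these genes and gave all genes the same spread beyond counting noise (dispersion 0.0017). In the data 61.3% of tested genes were called, so these rates may not carry over. Alternatives covered scaling, pseudocount, filters, the variance prior, limma-voom on rebuilt reads, a replicate block, thinning, the other deposited values, stricter thresholds and leaving out each library. The edgeR and DESeq2 tests planned for raw counts were not run. Plots and the remaining tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.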

Results

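The transcriptome of Huh7 hepatoma cells was measured 72 h after transfection with an siRNA against ASGR1 or with a scrambled control, with 3 libraries in each group. ASGR1 encodes the major subunit of the asialoglycoprotein receptor, which takes up desialylated glycoproteins in hepatocytes. The FPKM values rested on 16326000 to 19332000 fragments in the siControl libraries and 18481000 to 19257000 in the siASGR1 libraries. FPKM were above 0 for 26671 to 27300 genes in siControl and for 24609 to 25151 genes in siASGR1. Values are means ± SD in FPKM with n = 3 libraries per group unless stated, and adjusted p are from limma.

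The siRNA target was examined first. ASGR1 (ENSG00000141505; GRCh38 chromosome 17, 7173431 to 7179564, minus strand) was 17.3 ± 0.38 in siControl (17.54, 17.56 and 16.90). In the siASGR1 libraries the deposited sources gave different values. The table of the whole series gave 4.60, 4.82 and 4.71 (4.71 ± 0.11), which is 27.2% of siControl, with a log2 fold change of -1.68 (SE 0.04, adjusted p = 1.75e-06). The libraries' own files gave 14.65, 15.81 and 14.04 (14.8 ± 0.90), which is 85.6% of siControl, with a log2 fold change of -0.21 (SE 0.05, adjusted p = 0.00954). With median-of-ratios scaling, the difference from the own files was -0.08 (SE 0.06, adjusted p = 0.251) and no longer passed the test. No other gene of the 57905 differed between the sources, in any library, and the siControl values of ASGR1 were identical. Whether ASGR1 mRNA fell, and by how much, therefore rests on which deposited value and which scaling are used. With values as deposited, the same 8319 genes were called with either source.

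**Figure D1:**
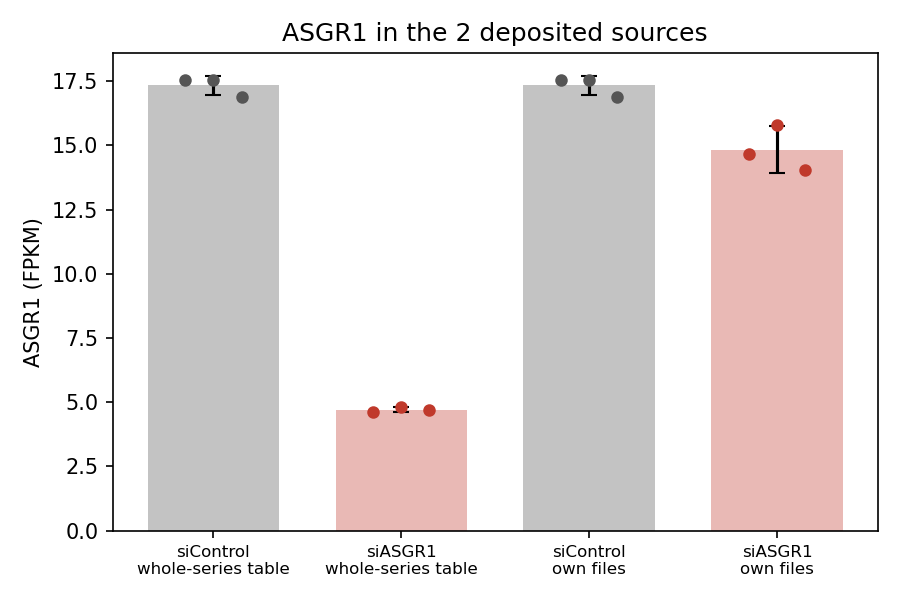
ASGR1 in FPKM by group in the table of the whole series and in the libraries' own files; points are libraries, bars are means and error bars are SD (n = 3). The siControl values are identical in both sources, while the siASGR1 libraries lie at 4.60 to 4.82 in the former and at 14.04 to 15.81 in the latter.

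Expression differed widely between the groups. Of 13568 genes tested, 2839 were higher and 5480 lower in siASGR1, and 259 of the higher and 503 of the lower genes changed at least 2-fold on the log2(FPKM + 1) scale. The split followed the scaling: it was 3958 higher and 4019 lower (364 and 355 at least 2-fold) with median-of-ratios scaling, which centres the median gene near 0, and 3890 and 4015 (367 and 318) with quantile normalization. With upper-quartile scaling it was 3406 and 4655 (305 and 420). The groups did not overlap for 9129 genes (67.3%), against 10% by chance. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.985 to 0.988 within groups and 0.942 to 0.945 between them. The first principal component (75.2% of variance) separated the groups.

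Among the largest increases were metallothioneins, small metal-binding proteins: MT2A rose from 3.55 ± 0.63 to 55.4 ± 4.50, MT1E from 0.053 ± 0.050 to 9.09 ± 0.46 and MT1G from 0.14 ± 0.24 to 7.78 ± 0.995. These genes are near-identical copies, so reads could be split between them and the single values are uncertain. The same caution holds for the histone genes H2BC12 (16.8 ± 1.79 to 99.5 ± 4.21), H2AC6 (2.39 ± 0.21 to 16.1 ± 0.27) and H2BC5 (2.39 ± 0.12 to 14.9 ± 0.64). NPPB, which encodes a natriuretic peptide, rose 8.29-fold in mean FPKM. ARG1, the urea cycle arginase, rose 7.41-fold, and the transcription factor gene CEBPD rose 5.25-fold. RNU7-45P, a short RNA gene, was listed at 0 in every siControl library and at 2.55, 3.44 and 4.95 in siASGR1. Its values are uncertain, since a few reads over a short gene give such FPKM. The adjusted p of the 12 genes with the largest increases, which also include APOB and FGB described with their lists, were at most 6.25e-05.

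The largest decreases included CDA, cytidine deaminase, from 14.1 ± 1.11 to 0.81 ± 0.19, and PGC, a pepsinogen, from 14.3 ± 0.59 to 0.89 ± 0.18. The long noncoding RNA UCA1 fell from 12.1 ± 0.56 to 0.76 ± 0.145. The endothelin receptor gene EDNRB fell from 5.41 ± 0.33 to 0.063 ± 0.047. CCN1, a secreted matrix protein, fell from 35.4 ± 0.77 to 5.49 ± 0.21 (adjusted p = 1.12e-06). EEF1A2, FUT3, INPP5J and LTBP4 were 8.63-fold to 11.2-fold lower in mean FPKM. The remaining 3 were short RNAs whose values are uncertain: MIR4254, listed at 0 in all siASGR1 libraries, and 2 Y_RNA copies, of which 1 was listed at 0 there.

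Genes controlled by LXR, the nuclear receptors that respond to oxysterols, were higher. Of 15 measured members 13 rose and 1 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 0.97 (camera adjusted p = 5.31e-08). With an estimated correlation the adjusted p = 0.0595, although the estimate (0.014) lay near the preset 0.01. Estimates were under 0.01 for cholesterol synthesis (-0.023), fatty acid synthesis (-0.019), fatty acid oxidation (-0.047) and cell cycle (-0.03). So were those for bile acids (-0.082) and acute phase (-0.039). Estimates were 0.115 for apolipoproteins, 0.184 for plasma proteins and 0.072 for glycolysis. A higher correlation therefore does not account for calls lost under 0.01, and the cause was not tested. The LXR list shares members with those of apolipoproteins (such as PLTP), fatty acid synthesis (such as SREBF1) and lipoprotein uptake (MYLIP). The results of these lists are therefore not independent. ABCA1 (ENSG00000165029; GRCh38 chromosome 9, 104781002 to 104928237), the cholesterol efflux transporter, rose from 3.50 ± 0.15 to 19.2 ± 1.59 (log2 fold change 2.16, SE 0.07). SREBF1, a regulator of fatty acid synthesis, rose from 11.1 ± 1.29 to 52.5 ± 1.86. NR1H3, which encodes LXRα, rose 2.31-fold, PLTP 2.12-fold and LPCAT3 2.2-fold. ABCG1 and ABCG8 rose 2.26-fold and 4.38-fold, whereas ABCG5 was 1.01 ± 0.13 and 1.12 ± 0.14 (adjusted p = 0.574; 0.0357 with quantile normalization). NR1H2, which encodes LXRβ, rose 1.2-fold (adjusted p = 0.0196), a call that was lost without siControl replicate 3 (adjusted p = 0.0578) and with no filter on low values (adjusted p = 0.0514).

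Cholesterol synthesis genes were mostly lower: 13 of 20 fell and 2 rose, with the same counts adjusted over the list alone and a median of -0.39. SQLE fell from 58.7 ± 2.26 to 27.0 ± 0.66, DHCR7 from 128.9 ± 7.97 to 67.7 ± 2.20, and HMGCS1 and LSS were 1.55-fold and 1.52-fold lower. The list passed camera narrowly (adjusted p = 0.0445). The call was lost with an estimated correlation (adjusted p = 0.156), although the estimate (-0.023) was below the preset 0.01. It was also lost with median-of-ratios (adjusted p = 0.0636) or upper-quartile scaling (adjusted p = 0.0563). The same held without siControl replicate 1 (adjusted p = 0.061), siControl replicate 2 (0.051), siASGR1 replicate 1 (0.0748) or siASGR1 replicate 3 (0.0611). Of the 16 genes of cholesterol sensing, 5 rose and 5 fell (adjusted over the list alone, 5 and 6; camera adjusted p = 0.308), against 8 and 3 with median-of-ratios scaling. SREBF2, the main regulator of cholesterol synthesis genes, fell from 87.1 ± 3.64 to 43.8 ± 0.35, and STARD4 was 1.56-fold lower. SOAT2, a cholesterol esterifying enzyme, rose 3.61-fold, and INSIG1 1.27-fold.

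Fatty acid and triglyceride synthesis genes rose in 13 and fell in 4 of 20 measured members, as they did adjusted over the list alone (median 0.38, camera adjusted p = 0.000778). The adjusted p = 0.07 with an estimated correlation. FASN, fatty acid synthase, rose from 127.6 ± 12.3 to 325.4 ± 0.99, FADS2 2.58-fold, FADS1 1.65-fold and SCD 1.33-fold, while ACSS2 was 1.93-fold lower. Fatty acid oxidation and PPARα target genes rose in 14 and fell in 2 of 19 (the same adjusted over the list alone; median 0.39, camera adjusted p = 2.61e-06). The adjusted p = 0.0595 with an estimated correlation. The lipid droplet coat gene PLIN2 rose 2.19-fold, ECI1 2.12-fold and ACAA1 1.53-fold.

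Apolipoprotein and lipoprotein assembly genes rose in 15 and fell in 1 of 17 measured members, also adjusted over the list alone (median 0.95, camera adjusted p = 3.56e-09). The adjusted p = 0.07 with an estimated correlation. APOB (ENSG00000084674; GRCh38 chromosome 2, 21001429 to 21044073), the structural protein of VLDL and LDL, rose 7.30-fold, from 74.3 ± 2.04 to 542.4 ± 60.9 (log2 fold change 2.85, SE 0.08, adjusted p = 2.03e-06). APOA2 rose 3.33-fold. Of 12 lipoprotein uptake genes, 5 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 0.116). The list passed with no filter (adjusted p = 0.0347) and with FPKM of at least 5 (adjusted p = 0.0358). MYLIP, a ubiquitin ligase gene, rose 1.79-fold, SCARB1, the HDL receptor, 1.67-fold, SDC1 1.38-fold and LRPAP1 1.39-fold.

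**Figure D2:**
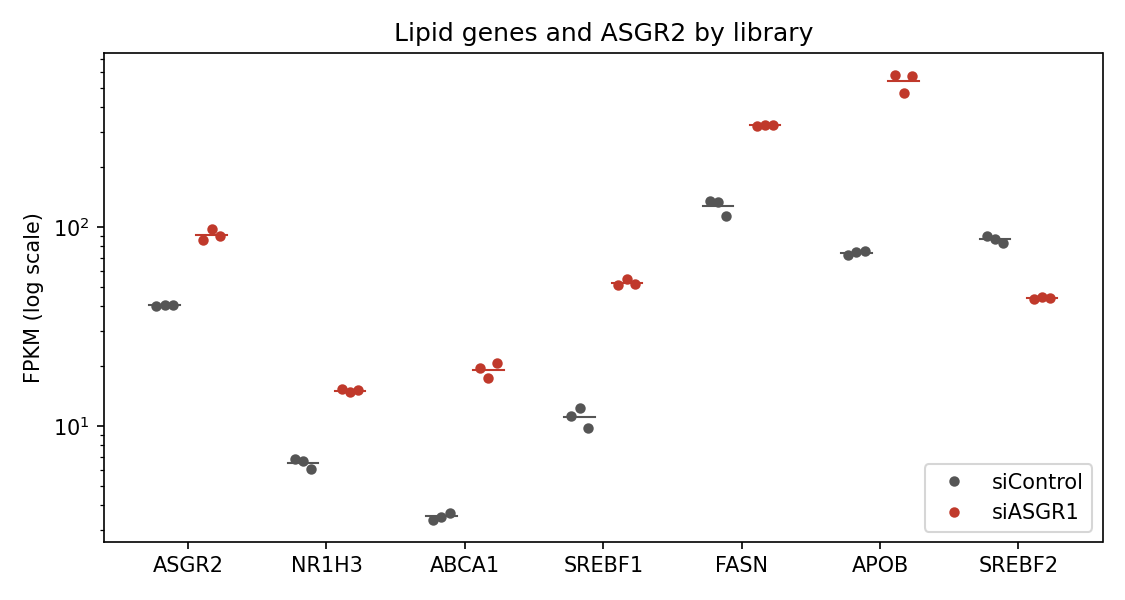
FPKM on a log axis of ASGR2 and 6 lipid genes in siControl (grey) and siASGR1 (red); points are libraries and lines are group means (n = 3). SREBF2 lies lower in siASGR1 and the other 6 genes higher, with no overlap between groups.

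Secreted plasma proteins of hepatocytes rose in 20 of 23 measured genes and fell in 0, also adjusted over the list alone (median 1.01, camera adjusted p = 1.79e-11). The adjusted p = 0.0894 with an estimated correlation. The fibrinogen chain genes FGB, FGA and FGG rose 5.32-fold, 2.92-fold and 2.37-fold, and SERPINA1, α1-antitrypsin, rose 2.11-fold. The 3 members not called were AMBP, VTN and F10, named after their values were seen. Acute phase and complement genes rose in 6 and fell in 3 of 14 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0174), against 10 and 2 with median-of-ratios scaling. The adjusted p = 0.125 with an estimated correlation, and 0.139 when FPKM of at least 5 were required. MBL2 and C8A rose 5.60-fold and 2.24-fold, while SAA1 was 4.29-fold lower. Hepatocyte and fetal liver identity genes went both ways, with 3 higher and 6 lower of 18 (the same adjusted over the list alone; camera adjusted p = 0.866), against 5 and 5 with median-of-ratios scaling. HNF4A, a hepatocyte nuclear receptor, rose from 29.9 ± 1.92 to 68.0 ± 0.18, AFP 1.63-fold and PCK1 1.49-fold, whereas FOXA2 was 1.81-fold lower.

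Bile acid synthesis and transport genes rose in 7 and fell in 3 of 12 measured members, as adjusted over the list alone (camera adjusted p = 0.00997). The adjusted p = 0.115 with an estimated correlation, and 0.139 when FPKM of at least 5 were required. The bile acid receptor gene NR1H4, the peroxisomal oxidase gene ACOX2 and the export pump gene ABCC2 rose 1.68-fold, 3.63-fold and 1.63-fold, and FGF19, a hormone that represses bile acid synthesis, was 2.97-fold lower. CYP7A1, the rate-limiting enzyme, was listed at 0 in all 6 libraries, which allows up to 0.053 to 0.062 FPKM. Of 21 genes of asialoglycoprotein handling and sialylation, 7 rose and 10 fell (the same adjusted over the list alone; camera adjusted p = 0.866), against 8 and 9 with median-of-ratios scaling. ASGR2 (ENSG00000161944; GRCh38 chromosome 17, 7101322 to 7115700), the other receptor subunit, rose from 40.4 ± 0.31 to 91.4 ± 5.76 and the galactosyltransferase gene B4GALT1 1.85-fold. The sialidase gene NEU1 was 2.74-fold lower and NANP 1.76-fold lower.

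Glycolysis and hypoxia genes rose in 17 and fell in 1 of 19 (18 and 0 with median-of-ratios scaling), also adjusted over the list alone (median 0.53, camera adjusted p = 1.43e-09). The adjusted p = 0.0638 with an estimated correlation. PFKL rose 3.07-fold, PGAM1 2.24-fold, TPI1 2.26-fold and ENO1 1.94-fold. Cell cycle genes rose in 17 and fell in 4 of 27, also adjusted over the list alone (median 0.30, camera adjusted p = 2.18e-05). The adjusted p = 0.0595 with an estimated correlation. The ribonucleotide reductase gene RRM2 rose from 17.6 ± 1.28 to 72.4 ± 0.61, and CCNB1, CCNB2 and MCM7 rose 1.51-fold to 1.68-fold.

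The BRCA1 complex and homologous recombination genes showed small differences, with 3 higher and 6 lower of 21 (2 and 5 adjusted over the list alone; camera adjusted p = 0.902). The balance turned with median-of-ratios scaling, to 5 higher and 2 lower. BRCA1 was 6.46 ± 0.23 and 6.13 ± 0.41 (adjusted p = 0.368), and its partner BARD1 was 4.72 ± 0.38 and 4.18 ± 0.059 (adjusted p = 0.0878). CHEK2 was 1.5-fold lower and PALB2 1.33-fold lower, and ATR rose 1.35-fold; the call of PALB2 was lost with quantile normalization (log2 fold change -0.125, adjusted p = 0.181). The 1.16-fold decrease of FANCA was not called with median-of-ratios (adjusted p = 0.302), upper-quartile (adjusted p = 0.0753) or quantile scaling (adjusted p = 0.338), without siControl replicate 1 (adjusted p = 0.0611) or without siASGR1 replicate 3 (adjusted p = 0.0554). Of 24 AMPK and mTORC1 genes, 3 rose and 11 fell (the same adjusted over the list alone), against 6 and 6 with median-of-ratios scaling (camera adjusted p = 0.866). CAB39 was 2.13-fold, PRKAB1 2.07-fold and RPS6KB1 1.61-fold lower, and RPTOR rose 1.52-fold.

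Stress-related lists did not pass camera as sets, although many of their members changed. Unfolded protein response genes rose in 9 and fell in 11 of 24 (adjusted p = 0.502): the chaperone genes HSPA5 and CALR rose 1.86-fold and 2.13-fold, whereas PPP1R15A and ATF3 were 2.30-fold and 4.58-fold lower. Of 21 ATF4 target genes 4 rose and 10 fell (adjusted p = 0.472), with ASNS, CHAC1, SLC7A11 and STC2 2.16-fold to 3.83-fold lower. Of 17 p53 targets 2 rose and 11 fell (adjusted p = 0.177). BTG2, ZMAT3 and GDF15 were 1.66-fold to 2.31-fold lower and TP53I3 rose 2.43-fold. Of 13 interferon response genes 2 rose and 9 fell (adjusted p = 0.171). USP18, IFI6 and ISG15 were 1.69-fold to 2.08-fold lower and IFI35 rose 2.32-fold. Of 23 lysosome and autophagy genes 5 rose and 8 fell (adjusted p = 0.902), with TFE3, GABARAPL1 and SQSTM1 1.41-fold to 2.10-fold lower. The counts adjusted over the list alone were the same for these 5 lists. With median-of-ratios scaling, the unfolded protein response had 11 higher and 9 lower, ATF4 targets 7 and 9, and lysosome genes 7 and 7, while p53 targets (2 and 10) and interferon genes (2 and 8) moved little.

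Of the lists that describe RNA quality, immediate early and heat shock genes rose in 4 and fell in 6 of 14 (the same adjusted over the list alone; camera adjusted p = 0.902), against 5 and 5 with median-of-ratios scaling. JUN was 3.01-fold and DUSP1 4.99-fold lower, and HSP90AA1 rose 2.34-fold. Mitochondrially encoded mRNAs rose in 5 and fell in 5 of 13, also adjusted over the list alone (camera adjusted p = 0.199), against 7 and 2 with median-of-ratios scaling. All genes with MT- symbols, not only these mRNAs, took 6.34% to 6.56% of rebuilt reads in siControl and 5.84% to 5.92% in siASGR1. MT-CO3 rose 1.57-fold, MT-CYB 1.21-fold and MT-ND1 1.22-fold, and MT-ND4L was 1.25-fold lower. None of these 4 was called when no filter on low values was applied (adjusted p = 0.0518, 0.216, 0.0803 and 0.258). MT-CYB showed no difference with quantile normalization. That method gives equal ranks equal values, so it can remove the difference of a gene whose rank stays the same, and this result cannot decide. Cytosolic ribosomal protein genes fell in 17 and rose in 2 of 30 (19 and 2 adjusted over the list alone; camera adjusted p = 0.177), but with median-of-ratios scaling only 4 were called lower and 3 higher. The list passed camera with quantile normalization (median -0.32, adjusted p = 1.7e-05), with no filter (adjusted p = 0.0201) and without siASGR1 replicate 2 (adjusted p = 0.0323). RPS27 was 1.60-fold lower, and RPL23, RPL15 and RPL18 1.2-fold to 1.3-fold.

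Among markers of other cell types, 4 of 12 fibroblast and stellate cell genes were measured, too few for the set test. COL1A1 fell from 2.46 ± 0.37 to 0.027 ± 0.006, COL1A2 from 1.51 ± 0.16 to 0.02 in each library, and TAGLN 2.51-fold, while PDGFRA rose 2.44-fold; the counts were the same adjusted over the list alone. Of 6 cholangiocyte and progenitor genes, 2 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.902), against 3 and 3 with median-of-ratios scaling. ANXA4 rose 3.10-fold, while SOX4, KRT19 and PROM1 were 1.52-fold to 1.9-fold lower. Of the 14 leukocyte markers only CD14 was measured (1.62 ± 0.47 and 1.62 ± 0.064), and no endothelial marker passed the filter. Of 16 epithelial and mesenchymal genes 5 rose and 6 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.472), against 7 and 2 with median-of-ratios scaling, with MMP14 and CDH2 1.27-fold to 1.43-fold higher and VIM 1.49-fold lower.

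**Figure D3:**
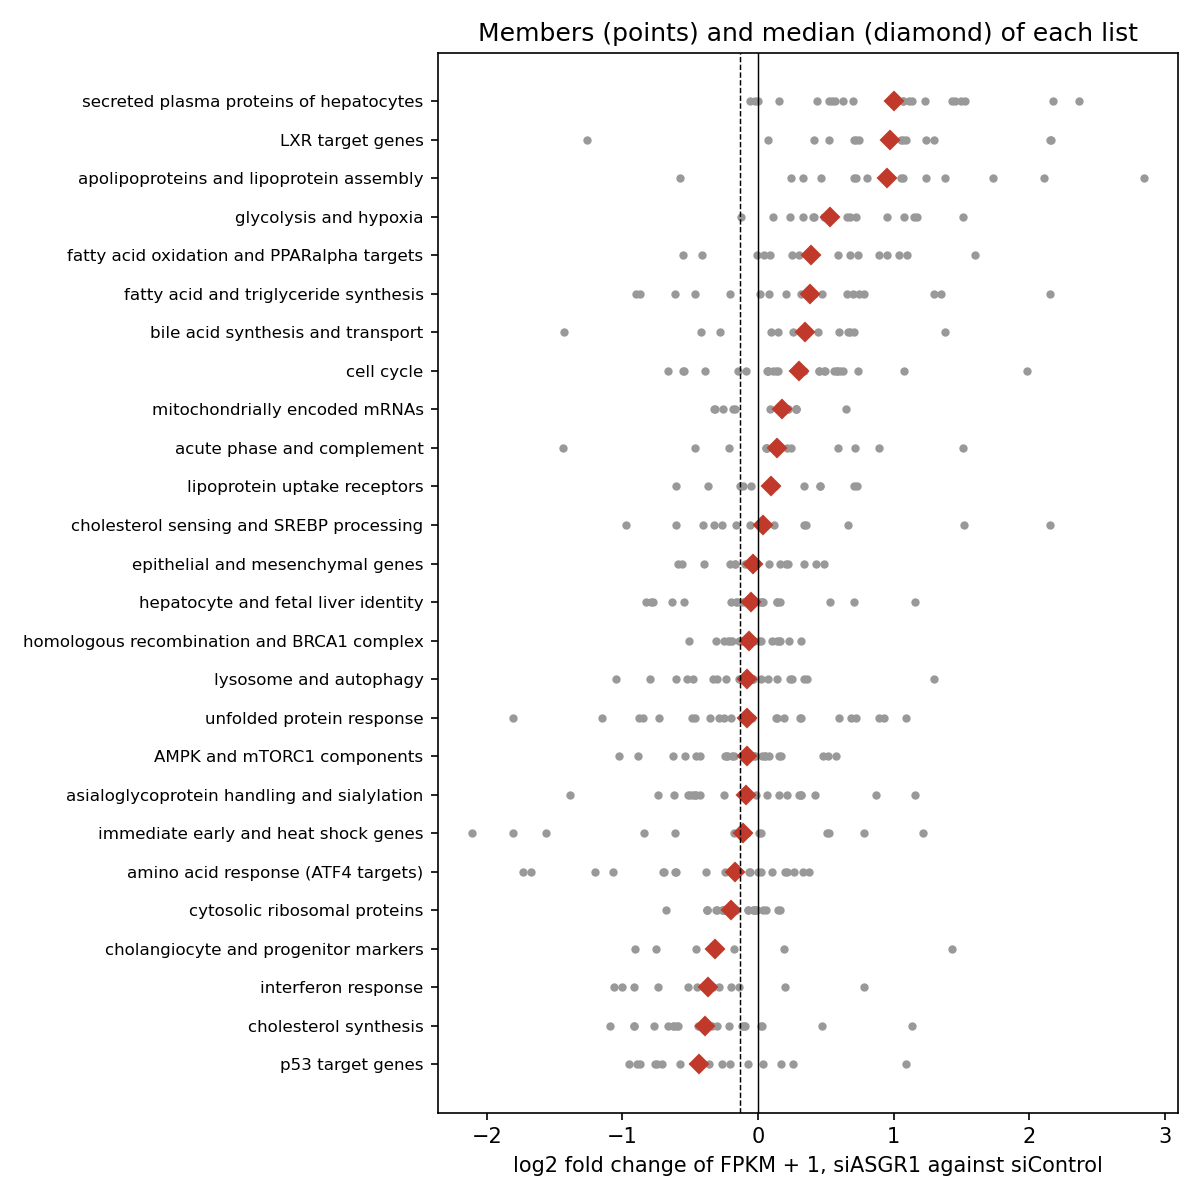
Log2 fold change (FPKM + 1) of each measured member (grey points) and the median (red diamond) of the 26 lists tested; the dashed line is the median of all tested genes (-0.13). Medians run from -0.44 for p53 targets to 1.01 for secreted plasma proteins.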

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

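The alternatives that changed the scaling, the pseudocount, the variance trend or the lowest FPKM to 5 were chosen after seeing the data. The number of called genes (8319) stayed within 1.5 times under all of them and under all others except a test against a fold change of 1.2, with 3898 called (1310 higher, 2588 lower). With FPKM of at least 5, 3382 genes were lower, 253 of them at least 2-fold, with 5578 genes called. Counts of genes changed at least 2-fold followed the pseudocount, which sets how far low genes are shrunk: 421 higher and 1102 lower with 0.1, and 87 and 75 with 5. They were 428 and 1114 with limma-voom on rebuilt reads, which changed the input, the weights and the offset at once, and the cause was not tested. Among genes changed at least 2-fold, the excess of lower genes turned with quantile normalization (367 higher, 318 lower) and median-of-ratios scaling (364 and 355). It also turned with a pseudocount of 5 (87 and 75), with the scaling unchanged, but not with upper-quartile scaling (305 and 420). The cause was not tested. Leaving out each library in turn gave 7445 to 7908 called genes.

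ASGR1 gave a log2 fold change of -0.21 with the own files and of -0.081, no longer called, with the own files and median-of-ratios scaling together; its other values ran from -1.88 to -1.20. Of 26 lists, 10 passed camera, 0 with an estimated correlation, 21 with directional fry, 26 with mixed fry and 19 with fry and the replicate block; fry tests whether a list's genes move, not whether they move more than other genes. Among lists that passed directional fry, the directions of fry and camera differed for asialoglycoprotein handling (median -0.092, with and without the block). They also differed for cholangiocyte markers (-0.32, without the block) and the unfolded protein response (-0.082, with the block). Without the block they also differed for lists not passing fry: hepatocyte identity (adjusted p = 0.0635), homologous recombination (0.106) and unfolded protein response (0.901). Camera called no direction for these. The median and camera also differ in sign for hepatocyte identity, homologous recombination and epithelial genes, since camera compares with all other genes, whose median is -0.13. MT-CYB was 0 with quantile normalization, which gives equal ranks equal values and so cannot decide here. Over 140 named genes and 22 alternatives, 27 comparisons lost and 7 gained a call, 3 and 1 of them on leaving out a library. The test against a fold change of 1.2 ended the calls of genes with small changes, among them NR1H2, INSIG1, ATR, PALB2, FANCA, CDH2, PROM1, MT-CYB, MT-ND1, MT-ND4L, RPL15, RPL18 and RPL23.

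Same-numbered libraries did not deviate together (correlations -0.019, 0.002 and 0.012), so the numbers were not taken to pair them. The replicate block called 8064 genes, and 9 lists by camera, with cholesterol synthesis lost (adjusted p = 0.0657). The gap between the lowest correlation within groups and the highest between them was 0.0405, and 0.2662 over the 500 most variable genes, chosen for their variance. The edgeR (with TMM) and DESeq2 tests planned for raw counts were not run, since the values are FPKM. Depth limits genes near 0, such as CYP7A1.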

Other observations

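The lists and tests in this paragraph were chosen after the largest changes had been seen. Of 17 measured target genes of YAP and TAZ, the coactivators of the Hippo pathway, 14 were lower and 1 higher (median log2 fold change -0.72). CCN2 fell from 99.3 ± 2.66 to 37.7 ± 1.23, ANKRD1 from 5.27 ± 0.92 to 0.49 ± 0.19 and AMOTL2 from 18.1 ± 0.43 to 6.94 ± 0.41 (mean FPKM ± SD, n = 3). All 5 measured metallothioneins were higher (median 2.96), as were 9 of the 11 listed replication-dependent histone genes (median 1.07), with H4C3 and H2AC20 not called. All 11 members of that list were measured, and histone genes outside it were not counted. Reads of these 2 families can be shared between copies.

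Some genes were nearly silent in 1 group. At FPKM of at least 1 in every siControl library and under 0.1 in every siASGR1 library there were 17 genes, 7 of them protein coding: COL1A1, COL1A2, SLC4A3, ADGRB2, ZCCHC12, DES and PLAC9. The reverse held for 3 genes, MT1B, RNA5SP301 and RNU7-45P. These thresholds were set after the values of some of the genes had been seen. Short RNAs in either direction, among them Y_RNA, MIR4254, MIR4319, RNA5SP203, RNA5SP301 and RNU7-45P, have uncertain values, since a few reads give such FPKM.

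Of the tests on the excess of lower genes, the one of scaling was chosen after the result was seen; the copy number test was added after the largest changes were seen, before its own result. A test written before the result argued against seed matches of the siRNA strand that pairs with the ASGR1 mRNA, where their shift is large enough to be found. Of the 7-mers of that mRNA, 0 had carriers shifted down at a Bonferroni p under 0.05, and the strongest ranked 3 of 16184 with a p of 1. A smaller shift, or that of a seed with few carriers, could have been missed. The other siRNA strand was not searched, and the labels give no siRNA sequence. The 3' UTRs of 85.7% of called genes and 79.9% of tested genes were searched, those of at least 30 bases. A limit of 80% on tested genes, set after the result was seen, had called the test void. The limit was then moved to called genes, also with the result known, and the test passed it. Scaling of FPKM to library totals stays open: 49.6% of called genes were higher with median-of-ratios scaling, in place of 34.1%, but that scaling centres the median gene near 0 and so evens the split whatever the cause. The real split called 8319 genes and 1 of the 10 splits of the libraries reached that. The highest of the others was 0 by limma (98 to 217 genes at an unadjusted p under 0.05). This test cannot decide, since it counts called genes rather than the balance of higher and lower. Each of the other splits mixes the groups, which widens the spread and leaves few calls. Moreover, 10 splits are too few for a share under 0.05. For cell populations that differ in copy number, 239 windows of 10 Mb were examined. The median of 1 window (chromosome 4, 30000001 to 40000000, 20 genes, median -0.48) lay further than 0.3 from that of all genes. In 1000 shuffles of the positions up to 3 windows did, and a loss of 1 of 4 copies was found in 90.4% of windows when planted. The rule set before the result asked for 0 such windows, so by it the test could not decide. The values do argue against losses of that size in many windows as the cause of the excess. Smaller shifts and the 1 window stay open.

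The higher plasma protein and lipoprotein mRNAs had a median log2 fold change of 0.97 over 40 genes. It was 1.07 with median-of-ratios scaling. After regression on transcript length, GC content and level the median residual was 1.00, measured from the fitted values rather than from 0. The median of all tested genes was -0.134 before the regression, so 0.97 and 1.00 are unlike measures. The 1.07 argues against scaling, and the 1.00 against this trend, as the whole cause. A response to the siRNA is a hypothesis that could account for the higher mRNAs. With 1 siRNA label and no rescue, an off-target effect or a difference between the cultures was not tested.

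Both tests on the ASGR1 values were chosen after the difference had been seen. The siASGR1 values of the own files were 2.98 to 3.28 times those of the table of the whole series. ASGR1 differed between the sources in 0 of the 3 siControl libraries, which argues against another gene model or another way of counting ASGR1 in all libraries of that table. At the GENCODE v29 exon length, 1 of the 3 siASGR1 values of that table lay further from a whole number of reads than rounding allows, and none of the own files' values did. That test cannot decide, since a value is whole by chance in 71.9% of cases and 59 of the 276 lengths that fit siControl make all values of the table whole, against 56 for the own files. Which value reflects the reads may be settled only from the reads, not used here.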
